A study of Mus musculus with 8 samples.

How the data were processed

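RNA was measured in neural stem and progenitor cells (NSPCs) sorted by flow cytometry from the cortex of mice at postnatal day 7. The iKO group carried a tamoxifen-inducible Cre recombinase under the Nestin promoter, a floxed Ash2l allele and a tdTomato reporter. The WT group carried the same Cre and reporter without the floxed allele. Each group had 4 libraries, and group and replicate number were taken from the sample titles. Per the labels' protocols, total RNA was amplified by Smart-Seq2, a full-length cDNA method, the cDNA was sheared by ultrasound, and the libraries were sequenced as paired ends on an Illumina HiSeq. The series design text calls the libraries biological replicates and does not say whether each came from 1 animal.

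The deposited values were TPM, an abundance scaled for transcript length and library total, for 55385 genes in each of the 8 libraries, and each column summed to 1000000. TPM values keep no sequencing depth, so the depth of each library is unknown. A second table deposited by the authors held their own iKO against WT comparison. Its headings, per the file headers, are those that DESeq2 writes. It gave a mean normalized signal per gene, a log2 fold change with its standard error, a test score, and an unadjusted and an adjusted p-value. The authors' mean normalized signal, per library, summed to 15443135 over all genes. Its log2 fold changes were computed by the authors as iKO over WT, per the file headers and name, and their direction was checked against the TPM values. The deposited adjusted p-value was 1 in 30307 rows and the fold change was empty in 25947 rows. The aligner, the quantifier, their versions and the genome build are not given in the sources used here, so no coordinates are printed. All 8 value columns could be matched to a sample by name.

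Because no counts per library were used, the main test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a mean-variance trend and robust moderation. Genes entered with a TPM of at least 1 in at least 4 libraries, which left 16413 genes. Fold changes are iKO minus WT on the log2(TPM + 1) scale, which understates the change of low genes. A gene was called changed at a two-sided Benjamini-Hochberg adjusted p of under 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists with at least 3 tested members. Camera with an estimated correlation and the rotation test fry were alternatives. Genes below the filter were compared by an exact two-sided permutation test of log2(TPM + 1) over the 70 assignments of 8 libraries, whose smallest possible p is 0.0286.

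The design, the 33 lists and the rule for naming genes were fixed before the data were examined. The rule named Ash2l and Onecut2. It also took the 12 largest rises and 12 largest falls among changed genes whose groups did not overlap and whose mean TPM was at least 5 in the higher group, leaving out predicted genes, pseudogenes and clone names. Up to 4 members of each list with the smallest unadjusted p could be named, as could the Onecut family and Tgfb1, Tgfb2, Tgfb3, Tgfbr1, Tgfbr2, Smad2, Smad3, Smad4 and Smad7.

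The procedure was tested on simulated data of 16015 genes for this comparison, with 50 genes changed by 0.25 log2 units, 49 each by 0.5, 1 and 2, and a list of 20 raised by 0.3. It recovered 40% of genes changed by 0.25 log2 units, 67.3% at 0.5, 93.9% at 1 and 98% at 2, and called 0.101% of unchanged genes. The simulation changed far fewer genes than the 52.6% called in the real data, and drew independent errors. With more changed genes the adjusted threshold is looser, so these rates do not carry over to the real comparison. Alternatives were the replicate number as a block, leaving out each library, pseudocounts of 0.1 and 5, no filter, a mean TPM of at least 5, trimmed mean of M values factors, quantile normalization, array quality weights, a sex score as covariate, a fold threshold, and the deposited comparison. The sex score was the mean log2(TPM + 1) of Ddx3y, Eif2s3y, Kdm5d and Uty minus that of Xist. Removal of a length and GC trend by loess (span 0.3) and a restriction to protein-coding genes of at least 1000 nt were added after seeing the data.

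Transcript lengths and sequences came from the GENCODE M21 annotation of GRCm38, which held 99.6% of the gene IDs; it may differ from the annotation the authors used. Near-identical copies were tested genes whose longest transcript matched at 95% identity or more over at least 50% of the shorter transcript (blastn 2.17.0, seqkit 2.13.0). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Marker lists for nasal epithelium, bone, mast cells, red blood cells and neutrophils, and lists of glucocorticoid-responsive and circadian clock genes, were written after the data had been seen. Not every gene that met the rule is printed, and 1 gene is not reported here.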

Results

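The data were TPM values of sorted cortical NSPCs from mice at postnatal day 7, with 4 iKO libraries, in which Ash2l was targeted by an inducible Cre, and 4 WT libraries. ASH2L is a core subunit of the complexes that methylate histone H3 at lysine 4. The depth per library is unknown. Between 16089 and 16616 genes reached 1 TPM in a library, and the 10 most abundant genes held between 9.47% and 10.5% of all TPM. The first principal component held 63.3% of the variance of the 500 most variable genes and separated the groups. Correlations of log2(TPM + 1) were 0.9871 to 0.9897 within groups and 0.9623 to 0.9645 between groups. Transcripts of both sexes were present in every library, with Xist at 15.4 TPM or more and Ddx3y at 22.5 TPM or more. No source used here ties a library to 1 animal, so the p-values measure only the spread between these libraries, which may be technical.

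The targeted gene, Ash2l (ENSMUSG00000031575.18), was lower in all 4 iKO libraries. Its level was 7.13 ± 0.714 TPM (SD, n = 4) in iKO and 17.6 ± 1.33 TPM (SD, n = 4) in WT, a log2 fold change of -1.20 (SE 0.0797, adjusted p = 3.82e-06). The authors' deposited table gave -1.15. Onecut2 (ENSMUSG00000045991.19), a homeodomain transcription factor gene named in the series title, stood at 0.0906 ± 0.0124 TPM in iKO and 0.224 ± 0.0292 TPM in WT (SD, n = 4). Every iKO value lay below every WT value (exact permutation p = 0.0286, the smallest possible). At these levels Onecut2 was below the filter of the main test. The authors' deposited table gave it a mean normalized signal of 24.4, a log2 fold change of -1.22 and an adjusted p of 7.73e-05.

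**Figure D1:**
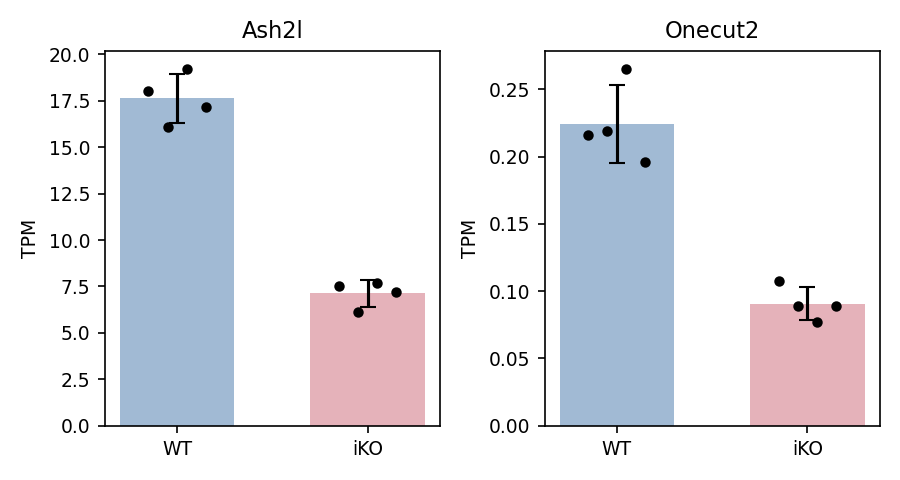
TPM of Ash2l (left) and Onecut2 (right) in WT and iKO libraries; bars are means, error bars are SD and points are the 4 libraries of each group. The iKO points lie below the WT points for both genes, at means of 7.13 against 17.6 TPM for Ash2l and 0.0906 against 0.224 TPM for Onecut2.

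Onecut1 stood at 0.04 TPM in iKO and 0.128 TPM in WT, which did not pass the test (exact permutation p = 0.0571). Onecut3 was listed at 0 in all 4 WT libraries and at 0.0519 to 0.154 TPM in iKO (exact permutation p = 0.0286). None of the 3 members of the family reached the filter.

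The comparison of iKO with WT asked which transcripts differ when Ash2l is deleted in these cells. Of 16413 genes tested, 8629 (52.6%) changed, 3392 higher and 5237 lower in iKO. Most changes were small: 68.2% of changed genes had an absolute log2 fold change under 0.5, and 561 reached 1, of which 196 rose and 365 fell. Groups did not overlap for 49.2% of tested genes, against 2.86% by chance. The median log2 fold change of all tested genes was -0.06. The split depended on scaling: 39.3% of changed genes were higher without scaling, 50% of 8506 with trimmed mean factors, 49.7% of 8408 with quantile normalization, and 53.4% of 8427 after removal of a length and GC trend. The authors' deposited table called 9969 genes, 5042 higher and 4927 lower. It shared 7054 genes with the calls made here, of which 99.1% had the same direction; both come from the same libraries.

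The largest rises included 4 genes of the Bpif cluster, which encodes secreted proteins of the upper airway. Bpifa1 stood at 68.5 ± 5.77 TPM in iKO (SD, n = 4) and was listed at 0 in every WT library, as were Bpifb3 (39.1 ± 4.62 TPM in iKO) and Bpifb6 (16.8 ± 1.44 TPM). Bpifb4 rose from 0.0655 TPM (0.0292 TPM without WT replicate 3) to 22.4 TPM. Ugt2a2, an olfactory glucuronosyltransferase gene, rose from 0.0873 to 11.8 TPM, and the carbonyl reductase gene Cbr2 from 6.85 to 40.7 TPM. The haemoglobin genes Hba-a1 and Hbb-bs rose from 21.3 to 519 TPM and from 11.5 to 157 TPM. The mast cell chymase gene Cma1 rose from 3.08 to 21.4 TPM, and the carboxylesterase gene Ces1d from 0.333 TPM (0.0804 TPM without WT replicate 4) to 5.62 TPM. Each of these had an adjusted p of at most 2.48e-05.

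The largest falls included Agt, the angiotensinogen gene expressed by astrocytes, which went from 726 ± 27.2 TPM in WT to 62.8 ± 2.69 TPM in iKO (SD, n = 4; log2 fold change -3.51, SE 0.0366, adjusted p = 1.35e-10). Mt2, a metallothionein gene, fell from 41.1 to 1.92 TPM. The potassium channel gene Kcnt1 fell from 18 to 1.28 TPM. Tmem144 fell by 3.27 on the log2 scale in TPM, while the authors' deposited table gave -1.07. Some genes of small mitochondrial and other proteins fell too: Atp5k from 198 to 13.5 TPM, Atp5j2 from 114 to 14.4 TPM, Cox6b1 from 213 to 43.8 TPM and Cops9 from 250.0 to 41.2 TPM.

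The values of genes with near-identical copies are uncertain, since the authors' counting could split their reads. The histone gene H2ac19 stood at 19.4 TPM in iKO and was listed at 0 in WT, while its copy H2ac18 stood at 0.684 TPM in iKO (0 without replicate 1) and 18.4 TPM in WT. Rn7s2, a 7S RNA gene, was listed at 0 in iKO and stood at 559 TPM in WT; with its copies the sums were 218 and 1122 TPM. Nme2 fell from 31.6 to 3.4 TPM, and its sum with the copy Gm20390 from 77.8 to 14.1 TPM. Ugt2a2 with its copy Ugt2a1 stood at 15.1 TPM in iKO and 0.0873 TPM in WT, and Hba-a1 with its copy Hba-a2 at 599.7 TPM in iKO and 58.5 TPM in WT. Rab26os, which lies on the opposite strand inside an intron of Rab26, was listed at 0 in iKO and stood at 5.8 TPM in WT. No near-identical copy of Rab26os was found, and the authors' deposited table gave it a mean normalized signal of only 1.81.

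TGF-β pathway genes were compared because the series title names this pathway. Of 34 tested target genes, 4 rose, 18 fell and 12 did not pass, with a median log2 fold change of -0.28 (camera adjusted p = 0.0163; adjusted p = 0.17 with an estimated correlation). Adjusted over the list alone, 4 rose and 19 fell. Ccn2, a matricellular protein gene, fell from 22.9 to 8.71 TPM, Cdkn1a, a cell cycle inhibitor gene, from 65.4 to 28 TPM, and Sparc from 771 to 567 TPM. Ccn1 fell from 615 to 475 TPM. Cdkn1a is also a member of the p53 target list and of the glucocorticoid-responsive list, so its fall counts in each. The call was also lost with the sex score as covariate, at a median of -0.216 (adjusted p = 0.058).

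Among 24 tested ligands, receptors and SMADs of the pathway, 5 rose and 7 fell, and the list was not called (adjusted p = 0.915). Adjusted over the list alone, 5 rose and 8 fell. Tgfb3 fell from 13.7 ± 0.666 to 9.07 ± 0.28 TPM, and Tgfbr2 rose from 7.77 ± 0.459 to 10.6 ± 0.591 TPM (SD, n = 4). The endothelial co-receptor gene Eng rose from 56.2 to 81.3 TPM and Acvr2b from 18.9 to 23.4 TPM. Smad3 fell from 7.06 to 5.92 TPM, a call lost with quantile normalization (adjusted p = 0.186) and after removal of a length and GC trend (adjusted p = 0.102). Tgfb2 (25.7 and 27.6 TPM in iKO and WT), Tgfbr1 (12 and 13.6 TPM), Smad2 (35.7 and 38.4 TPM), Smad4 (40.5 and 45.9 TPM) and Smad7 (2.02 and 1.46 TPM) did not pass. Tgfb1 stood at 0.397 and 0.343 TPM (exact permutation p = 0.657).

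Astrocyte markers fell as a list: 3 of 18 rose, 13 fell and 2 did not pass, with a median log2 fold change of -0.41 (camera adjusted p = 0.000277; adjusted p = 0.29 with an estimated correlation). Besides Agt, the cytoplasmic protein gene Ndrg2 fell from 932 to 535 TPM, Mlc1 from 1018 to 691 TPM and Clu, the clusterin gene, from 2041 to 1429 TPM. Of 23 neural stem cell and radial glia markers, 3 rose and 13 fell, and the list was not called (adjusted p = 0.113). Slc1a3, a glutamate transporter gene, fell from 2039 ± 33.3 to 1241 ± 27 TPM, and Fabp7, a fatty acid binding protein gene, rose from 664 ± 18.3 to 925 ± 12.4 TPM (SD, n = 4). Ptprz1 and Cd9 fell by 0.34 and 0.31 on the log2 scale.

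Neuroblast and immature neuron markers went both ways, with 12 of 23 higher and 6 lower (median log2 fold change 0.17, camera adjusted p = 0.0169; adjusted p = 0.412 with an estimated correlation). Dcx, a microtubule protein gene of migrating neurons, rose from 137 to 185 TPM and Sp8 from 198 to 244 TPM, while Sox11 fell from 391 to 219 TPM and Cd24a from 370 to 272 TPM. Quantile normalization ended this call at a median of 0.162 (adjusted p = 0.0864), as did the sex score at 0.072 (adjusted p = 0.57). Transit-amplifying and intermediate progenitor markers (3 of 14 higher, 5 lower, adjusted p = 0.902) and mature neuron markers (7 of 20 higher, 7 lower, adjusted p = 0.393) were not called. Btg2 fell from 926 to 633 TPM, Dlx2 rose from 350 to 495 TPM and Camk2a rose from 11 to 37.7 TPM. In these same libraries, Y-linked genes, endothelial markers and blood markers differed between the groups.

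Endothelial markers rose in 15 of 18 cases, with none lower and a median log2 fold change of 0.62 (camera adjusted p = 3.82e-08; adjusted p = 0.0505 with an estimated correlation). Cldn5, a tight junction gene, rose from 335 ± 4.37 to 627 ± 15.8 TPM and Flt1, a VEGF receptor gene, from 19 ± 1.06 to 36 ± 2.04 TPM (SD, n = 4). All 7 tested blood cell markers rose, at a median of 1.88 (camera adjusted p = 0.000127; adjusted p = 0.0505 with an estimated correlation). Microglia and macrophage markers fell in 13 of 20 cases and rose in 3 (median -0.34, camera adjusted p = 0.036; adjusted p = 0.359 with an estimated correlation). Tmem119 fell from 26.7 to 13 TPM and P2ry12 from 43.4 to 25.9 TPM. The microglia call was lost with the sex score as covariate, at a median of -0.243 (adjusted p = 0.125).

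**Figure D2:**
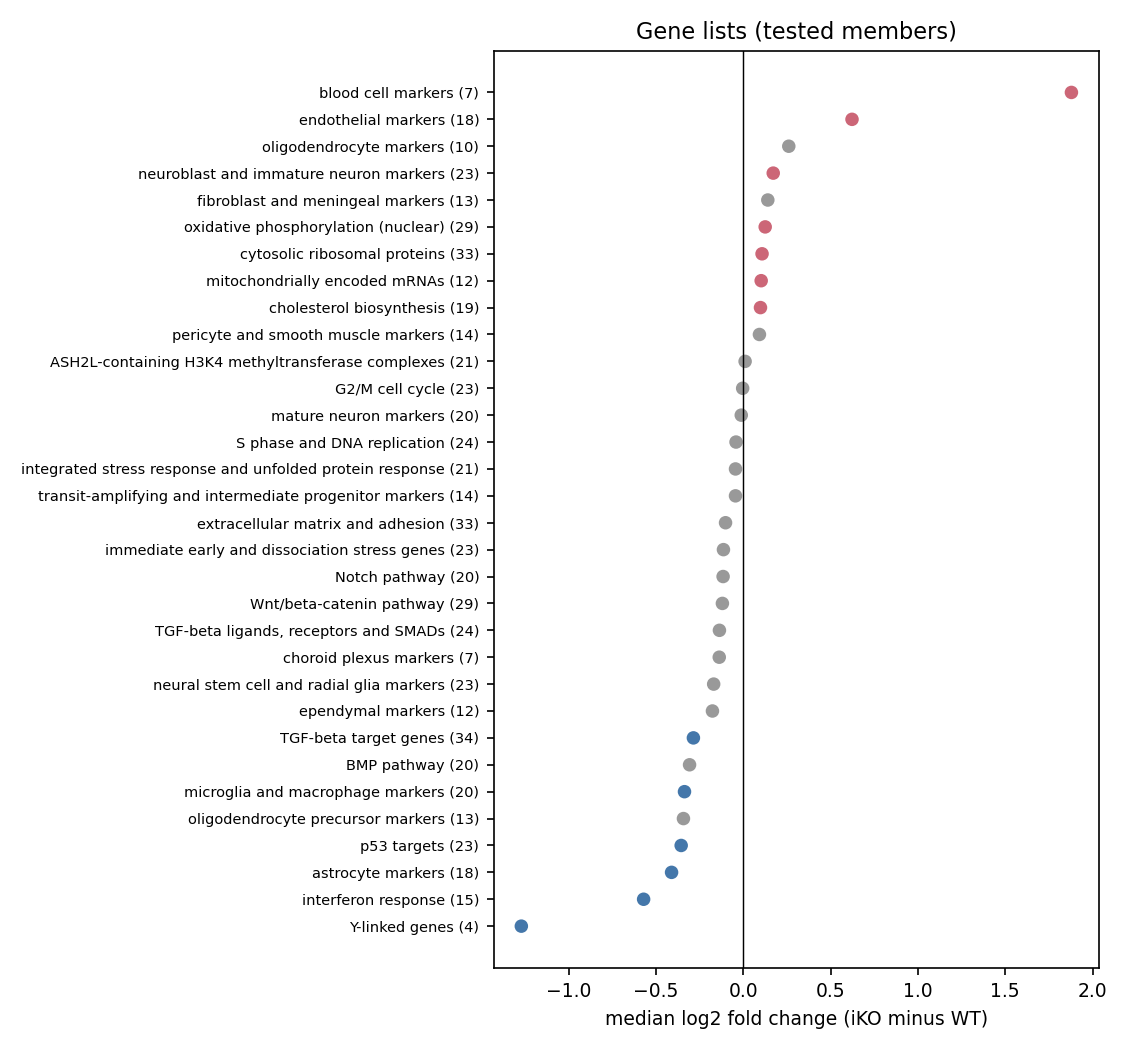
Median log2 fold change of the tested members of each gene list, iKO minus WT on the log2(TPM + 1) scale; the number of tested members stands in parentheses. Red points are lists called higher, blue points lists called lower and grey points lists not called by camera at the preset correlation; endothelial markers lie at 0.62 and astrocyte markers at -0.41.

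The p53 target list fell in 16 of 23 cases and rose in 1 (median -0.35, camera adjusted p = 0.00674; adjusted p = 0.17 with an estimated correlation). Sesn1 fell from 132 to 74.4 TPM and Perp from 8.52 to 4.43 TPM, while the apoptosis effector gene Bax rose from 361 to 471 TPM. Interferon response genes fell in 12 of 15 cases and rose in 1 (median -0.57, camera adjusted p = 0.000346; adjusted p = 0.0505 with an estimated correlation). The major histocompatibility class I genes H2-K1 and H2-D1 fell from 188 to 94.8 TPM and from 102 to 53.9 TPM, and B2m from 291 to 203 TPM.

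In the list of nuclear oxidative phosphorylation genes, 14 of 29 rose and 7 fell (median 0.13, camera adjusted p = 0.00271; adjusted p = 0.0577 with an estimated correlation). Atp5k, Atp5j2 and Cox6b1, also nuclear genes of oxidative phosphorylation but outside the list, were among the largest falls given above. Ndufs4 rose from 155 to 290.0 TPM and Cox5a from 357 to 520 TPM. The authors' deposited table gave a log2 fold change of 0.444 for Ndufs4, a smaller rise than in TPM, and 0.61 for Cox5a. Cholesterol biosynthesis genes rose in 9 of 19 cases and fell in 2 (median 0.10, camera adjusted p = 0.00822; adjusted p = 0.17 with an estimated correlation), a call lost with quantile normalization at a median of 0.107 (adjusted p = 0.0864); Mvd rose from 54 to 82.6 TPM. Cytosolic ribosomal protein genes had 15 of 33 higher and 10 lower, with a median of 0.11 and a mean of -0.12 (camera adjusted p = 0.0438; adjusted p = 0.497 with an estimated correlation), and the call was lost with trimmed mean factors (adjusted p = 0.0853), quantile normalization (0.23), the sex score (0.386), the replicate block (0.0699), a mean TPM of at least 5 (0.0809) and the length and GC trend removed (0.214). It was also lost without any of iKO replicate 4 (0.0564) and WT replicates 2 (0.0809), 3 (0.065) and 4 (0.062). Its median under these settings was 0.079 to 0.172. Rpl14 rose from 282 to 448 TPM. Mitochondrially encoded mRNAs had 7 of 12 higher and 2 lower, with a median of 0.10 and a mean of -0.04 (camera adjusted p = 0.0373; adjusted p = 0.497 with an estimated correlation). That call was lost without iKO replicate 4 (adjusted p = 0.0507), WT replicate 2 (0.0777) or WT replicate 3 (0.0539), with quantile normalization (0.0864), the sex score (0.435), a mean TPM of at least 5 (0.0658) and fry (0.0614), at medians of 0.07 to 0.109, and mt-Atp8 fell from 806 to 280 TPM.

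The 4 Y-linked genes were lower in iKO, at a median log2 fold change of -1.27 (camera adjusted p = 0.0169; adjusted p = 0.368 with an estimated correlation). Ddx3y stood at 23.6 ± 1.26 TPM in iKO and 53.8 ± 3.3 TPM in WT (SD, n = 4), and Xist at 18.9 to 20.1 TPM in iKO and 15.4 to 16.9 TPM in WT. The sex score separated the groups completely, from -0.82 to -0.26 in iKO and from 0.56 to 1.01 in WT. With the score as covariate the Y-linked list, whose genes enter the score, lost its call (median 0.064, adjusted p = 0.804), 423 genes changed, 195 higher and 228 lower, and the fold change of Ash2l was -1.07 with an adjusted p of 0.142.

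**Figure D3:**
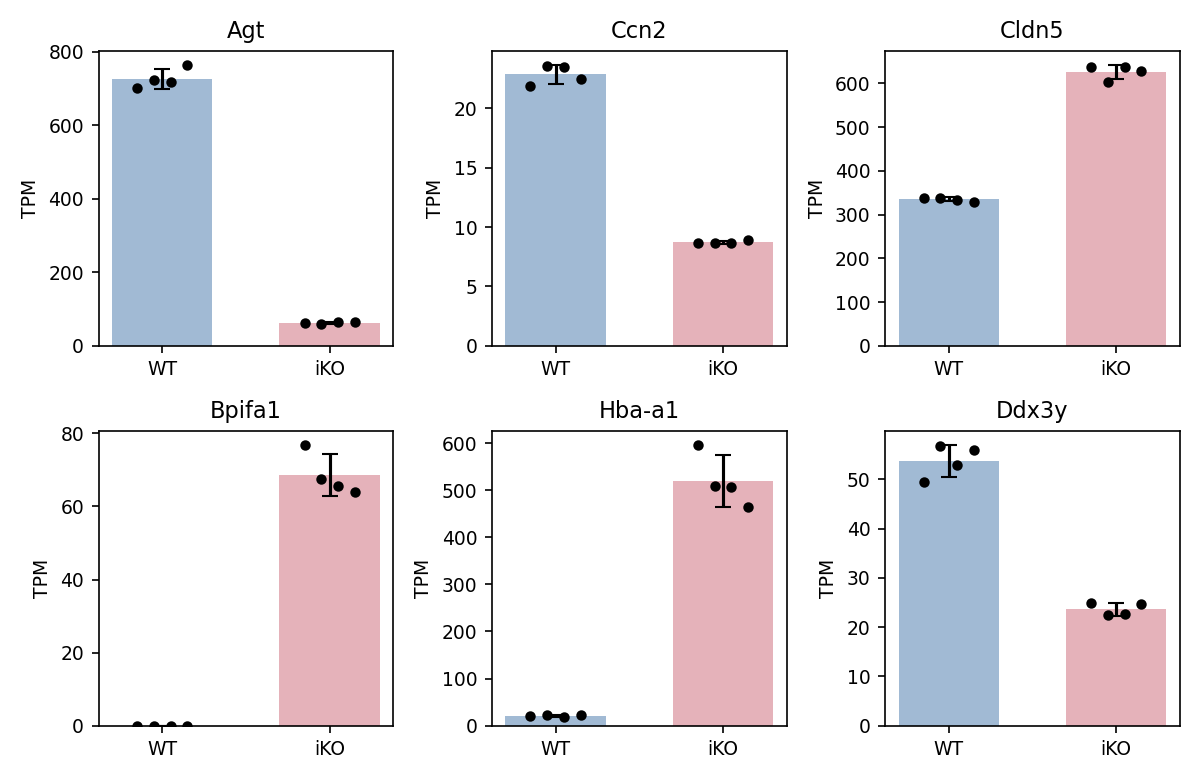
TPM of Agt, Ccn2, Cldn5, Bpifa1, Hba-a1 and Ddx3y in WT and iKO libraries; bars are means, error bars are SD and points are the 4 libraries of each group. Agt, Ccn2 and Ddx3y are lower and Cldn5, Bpifa1 and Hba-a1 higher in every iKO library than in every WT library.

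The other lists were not called. ASH2L-containing complexes had 6 of 21 members higher and 3 lower (adjusted p = 0.393), with Dpy30 rising from 92.5 to 140 TPM. BMP pathway genes had 2 of 20 higher and 12 lower (adjusted p = 0.0649), and Id3 fell from 1086 to 871 TPM. Wnt pathway genes had 4 of 29 higher and 13 lower (adjusted p = 0.393), with Nkd1 rising from 31.4 to 54.9 TPM and Dkk3 falling from 220 to 126 TPM. Notch pathway genes had 1 of 20 higher and 9 lower (adjusted p = 0.209), and Dll3 fell from 194 to 134 TPM. Oligodendrocyte precursor markers had 2 of 13 higher and 8 lower (adjusted p = 0.133), and oligodendrocyte markers 5 of 10 higher and 3 lower (adjusted p = 0.133); Mbp rose from 49.2 to 99.1 TPM. G2/M genes had 4 of 23 higher and 4 lower (adjusted p = 0.451), and S phase genes 5 of 24 higher and 6 lower (adjusted p = 0.822), with Birc5 rising from 167 to 249 TPM and Pcna falling from 37.2 to 20.8 TPM. Extracellular matrix and adhesion genes had 4 of 33 higher and 14 lower (adjusted p = 0.272), and Bcan fell from 1771 to 1093 TPM. Immediate early genes had 6 of 23 higher and 13 lower (adjusted p = 0.11), with Fos falling from 7341 to 5300 TPM. Stress response genes had 7 of 21 higher and 8 lower (adjusted p = 0.962), and Sdf2l1 rose from 81.4 to 160 TPM. Pericyte markers (6 of 14 higher, 4 lower, adjusted p = 0.275), fibroblast markers (5 of 13 higher, 4 lower, adjusted p = 0.519), ependymal markers (4 of 12 higher, 5 lower, adjusted p = 0.881) and choroid plexus markers (none of 7 higher, 2 lower, adjusted p = 0.656) completed the lists.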

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

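The tests of other splits, and the test of epithelial genes whose values had not been looked at, were set before their results were seen; the other tests of the 3 patterns were chosen after. The test of epithelial genes replaced an earlier form that used genes already seen and a wrong chance level. Of the 35 splits of the 8 libraries into 4 and 4, only the real one, 1 split, gave as many genes changed as the 8629 observed, and the highest of the other splits gave 3. For genes higher and for genes lower the count was also 1 of 35. The highest other split gave 3, taking in each split whichever direction held more genes. For the 13 lists called the count was 1 of 35, with 10 in the highest other split. A count of 1 of 35 is the smallest possible here, so these tests argue against chance in the grouping only to that degree. Mixed splits carry the large group difference as spread, so their low gene counts were largely fixed in advance. A difference between the groups other than genotype is not excluded.

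Libraries of a group differed little. Over 3570 genes with at least 1000 mean counts in the deposited table, the coefficient of variation within groups beyond counting error was 2.44%. Pairs of libraries had 1.89 to 3.28 times the variance of counting error, so no pair was treated as 1 library. Counting error was estimated from the deposited mean normalized signal, as if libraries of a group had equal depth. The depth of each library is unknown, so the 2.44% and these ratios are approximate. The lowest Xist level of 15.4 TPM beside the lowest Ddx3y level of 22.5 TPM argues against the RNA of 1 animal in each library. Whether the 4 libraries of a group came from 1 common pool (2.44%) or from separate pools of several animals (SD of the sex score within groups 0.214) cannot be told apart. The score was expected to vary by 0.104 from genes of the same level, which goes toward separate pools, but its spread rests on 5 genes and the technical spread of the amplification is unknown. Y-linked transcripts were lower in iKO, and a different sex mix was not separated from an effect of genotype on them. No biological explanation of the small spread was tested.

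Of the detected markers, 16 of 21 nasal genes outside the Bpif cluster, 6 of 6 red blood cell genes, 5 of 8 neutrophil genes and 4 of 9 mast cell genes lay higher in all 4 iKO than in all 4 WT libraries, while 2 of the nasal and 2 of the mast cell genes lay lower. The rise was not confined to the Bpif gene cluster: 11 nasal genes outside it had a log2 fold change above 1 and separate groups. Among them were Cyp2a5 (5.3 against 0.302 TPM) and Cyp2g1 (3.51 against 0.0798 TPM). That list was written after the data had been seen and holds genes already seen to rise. Its count describes the pattern and is no test of switching on of the cluster alone. Carry-over of tissue next to the brain may account for the pattern. Of 18 detected epithelial genes whose values had not been looked at, 33.3% lay higher in all 4 iKO libraries. Random lists of like TPM gave 7.56% (gene permutation p = 0.0013). That p came from random draws of genes, not of libraries, and treats genes as independent. Genes that vary together would make it too small. Aqp5 stood at 4.17 TPM in iKO and 0.806 TPM in WT. Grhl1, the 1 of the 18 at 1 TPM or more in WT, lay lower in all 4 iKO libraries (4.02 and 6.53 TPM). A sort for the reporter should remove such cells, and Obp1a, Obp2a and Cyp2a4 were listed at 0. A genotype effect within the sorted cells, seen in 4 of 4 iKO libraries, stays open, since carry-over in each iKO preparation would look alike.

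Large folds were concentrated in short genes and pseudogenes: 26.4% of protein-coding genes under 600 nt changed with an absolute log2 fold change of at least 1, against 1.05% of those of 4000 nt or more. Of the 167 members (under 1000 nt or pseudogene, mean TPM of at least 5), 40.1% were higher in iKO. This argues against a lower recovery of short transcripts in one group as the account of these folds. For 1.2%, the fold in the authors' deposited table was under 50% of that in TPM or of the other sign. The pseudocount shrinks the TPM folds of low genes, and a length shared by both groups cancels from a fold. The low share shows that these folds were not confined to TPM, but decides little about division by transcript length. A graded shift with length was present over protein-coding genes, from a median log2 fold change of 0.208 at 600 to 1000 nt to -0.086 at 4000 nt or more. After removal of the length and GC trend, 97% of the 167 kept a called fold of at least 1 in the same direction. Their median absolute log2 fold change was 1.62 before and 1.59 after. The trend was small beside folds chosen to be at least 1, so few could drop below 1. The values say only that a smooth trend of this size was not the account of these folds. The shift itself stays open as a difference in recovery. No near-identical copy was found for 93 members. Of the other 74, 41 had copies whose own change left room for an offset, and copies offset over 50% of the TPM change in 19.5% of the 41 (upper 95% limit 34.9%; 11.4% with random partners). This argues against an offset of over 50% by copies for most of the 41. A smaller offset was not scored, so a partial division of reads among copies stays open for them. Over all 74, the copies moved the other way for 34 members. A different division of reads also stays open for 33 members. Their copies changed by 1.5 times as much or more, which fixes the outcome of the test. A copy was more frequent among the 167 (44.3%) than among other short genes and pseudogenes (22.8%), which goes with sharing. An earlier form of that test, which asked whether summing copies reduced the fold, was dropped because an unchanged copy also dilutes a fold. No source used here says whether both groups were aligned and counted alike. A difference there would change what these folds mean and cannot be told apart from genotype: 12 members were listed at 0 in all 4 libraries of one group, 7 of them with a copy. Ash2l deletion itself stays open for these genes, untested.

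Single libraries were flagged by the gap to the nearest other value as a share of the range of the 4 values of a group. The size of the difference did not enter, and some were small, as for Id3 (1099 TPM against 1081 to 1083 TPM). Over the named genes, 21 of the 307 groups of 4 values were flagged, where chance gives about 15.4, and 20 of them are listed here. In WT replicate 4 these were Ccnb2 (7.38 TPM), Ces1d (1.09 TPM), H2-K1 (193 TPM), H2ac18 (23.3 TPM), Id3 (1099 TPM), Nefl (2.37 TPM) and Nme2 (37.5 TPM). In WT replicate 3 they were Birc5 (172 TPM) and Vcan (60.8 TPM). In WT replicate 2 they were Dpy30 (81.9 TPM), Dynlrb2 (30.9 TPM) and Eng (65.6 TPM). Among iKO libraries, replicate 1 stood apart for H2ac18 (2.73 TPM), Slc1a3 (1201 TPM) and Tgfbr1 (14.3 TPM), and replicate 2 for Dll3 (128 TPM) and Mal (8.64 TPM). Replicate 3 of iKO stood apart for Eng (77.5 TPM), and replicate 4 for Ccn2 (8.93 TPM) and Smad4 (34.9 TPM).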

How the results depend on the processing

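Genes changed ranged from 7808 to 8003 when 1 library was left out. With the sex score as covariate, 423 genes changed (195 higher, 228 lower), 7 lists were called and Ash2l stood at -1.07 (adjusted p = 0.142, against at most 4.8e-05 under its other settings); the score separates the groups, so little of the difference remains to be tested. Requiring an absolute log2 fold change of at least 1 left 561 genes (196 higher, 365 lower), and 460 shared with the deposited table. Camera with an estimated correlation called 0 lists (7 at an unadjusted p under 0.05), and fry 24. The first component held 60.6% to 63.9% without 1 library, lowest without WT replicate 4. The replicate number as a block gave 8097 changed genes, 7794 of them shared, and the ribosomal list lost its call; same-numbered libraries did not deviate together (correlations -0.044 to 0.001, and 0 of 8 correlated best with their own number).

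Of 2846 named-gene comparisons, 2726 kept direction and side of the threshold, 91 lost significance, 18 gained it and 11 reversed; for lists the counts were 594, 36, 19 and 21 of 670. Reversed under the sex score were Crabp2 (-0.221), Otx2 (0.207), Hbb-bt (-0.533), Rfc2 (-0.006), Uty (0.34), Kdm5d (0.605), Tgfbr1 (0.081) and Smad7 (-0.066). Tgfb1 ranged from -0.033 without WT replicate 4 to 0.149 without 1 library. With the length and GC trend removed, Tgfb2 was at 0.002 and Smad2 at 0.026. The lists whose direction in the set test turned were all ones not called, and their medians were as follows. Under the sex score these were 0.08 for choroid plexus, -0.147 for G2/M, -0.072 for S phase and -0.077 for stress response. With quantile normalization they were -0.048 for TGF-β ligands, -0.015 for S phase and -0.049 for stress response, and with trimmed mean factors 0.007 for transit-amplifying markers. TGF-β ligands stood at -0.032 with the trend removed and -0.1 at a mean TPM of at least 5. Stress response stood at -0.053 both without the filter and for longer protein-coding genes, where ependymal markers stood at 0.142. With fry, ASH2L complexes stood at 0.011, S phase at -0.041 and stress response at -0.044. Leaving out 1 library gave -0.085 to -0.027 for transit-amplifying markers, -0.052 to -0.011 for stress response and -0.152 to -0.1 for TGF-β ligands. The cause was not tested.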

Other observations

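The list of glucocorticoid-responsive genes described first, and the clock list, were chosen after seeing the data; the test on genes whose values had not been looked at was set before its result was seen, and replaced an earlier form on genes already seen. Genes known to respond to glucocorticoids were lower in iKO, with 25 of 30 tested members lower and 2 higher (median log2 fold change -0.71, and -0.65 with quantile normalization). Fkbp5, which encodes a co-chaperone of the glucocorticoid receptor, stood at 8.31 ± 0.173 TPM in iKO and 29.6 ± 1.84 TPM in WT (SD, n = 4), Tsc22d3 at 142 and 296 TPM, and Glul, the glutamine synthetase gene, at 153 and 316 TPM. Circadian clock genes were lower too, 14 of 16, among them Nr1d1 (23.3 and 45.9 TPM) and Arntl (22.3 and 31.1 TPM).

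A hypothesis from this is that glucocorticoid-responsive genes were lower as a class. In a separate list of such genes whose values had not been looked at, 16 of 19 tested members were lower and 1 higher (median -0.44), and camera with an estimated correlation gave p = 0.00346, which is consistent with it. Htra1 stood at 1011 and 1901 TPM in iKO and WT, Gpd1 at 51.2 and 99.7 TPM and Slc10a6 at 0.123 and 4.73 TPM. The test does not separate genotype from the hormone level or handling of the animals, which no source used here describes, and astrocytes also express many of these genes.

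In the marker lists written after the data had been seen, all 4 iKO libraries lay above all 4 WT libraries for 4 of 5 detected Bpif cluster genes, 16 of 21 other nasal genes, 6 of 6 red blood cell genes, 5 of 8 neutrophil genes, 4 of 9 mast cell genes and 4 of 10 bone genes. Random lists of like TPM gave 15%, 9.56%, 21.3%, 11.5%, 12.9% and 16.8%. Genes already seen to rise, such as Bpifa1 and Hba-a1, are among the members, so these shares describe the pattern and do not test it. The bone list, at 40%, did not pass the threshold of 0.05 (gene permutation p = 0.063). That p also came from random draws of genes, not of libraries, and treats genes as independent. Spp1, Ibsp and Dmp1 stood at 284, 8.46 and 7.91 TPM in iKO and 95.5, 2.17 and 2.56 TPM in WT. Alpl (42.8 and 47.1 TPM) and Omd (2.53 and 3.07 TPM) were lower in all 4 iKO libraries. Among mast cell genes, Cpa3 was at 35.3 and 6.89 TPM, while Hdc (28.5 and 32.3 TPM) and Tpsab1 (0.979 and 2.15 TPM) were lower in iKO.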
